A study of Rattus norvegicus with 36 samples.

How the data were processed

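RNA was measured in PFC and NAc tissue of 19 Sprague Dawley rats as 36 libraries. Per the labels' protocols, total RNA was extracted with miRNeasy, prepared with TruSeq RNA version 2 and sequenced on a NovaSeq instrument as 101-bp paired-end reads. Trimmomatic, STAR 2.5.3a, HTSeq 0.9.0 and edgeR, with the Rnor_6.0 and rn6 builds, are named per the submitters' processing notes. The annotation release and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies are uncertain. The deposited values are raw counts per gene, whole numbers for 32623 Ensembl identifiers in each file, with 5 HTSeq summary categories that were kept out of library sizes and gene tests. Of the identifiers, 6713 were at 0 in every library. No normalisation had been applied to the deposited counts.

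Library depth and the read categories were taken from the same files. Counts over genes ranged from 18436025 to 34761269 per library. The unassigned share is the count that HTSeq gave to no annotated feature, over that count plus gene and ambiguous counts. It ranged from 22.1% to 33.0%. Whether it includes reads within introns of annotated genes cannot be told from the counts. This denominator was settled after the data were seen. A first version over all alignments is among the alternatives. The ambiguous share ranged from 0.601% to 0.779% of gene-overlapping pairs, and the not-unique share from 12.0% to 13.8% of all alignments. Groups were compared by a two-sided exact permutation test of the difference in means over 48620 regroupings, with Benjamini-Hochberg adjustment over 12 tests.

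Groups follow the labels for region and preference. Animals were identified from the sample titles. Over the 144 pairs of libraries within groups, counts differed by 7.00 to 46.2 times the sampling noise (chi-square per degree of freedom), so none of these pairs was a repeat deposit. Libraries of different groups were not compared in this way. Titles pair the regions of 17 animals. The deviations of their libraries from group means correlated at 0.138 to 0.493, and each of the 17 NAc libraries correlated best with the PFC library of its own animal.

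Within each region, genes passing filterByExpr were scaled by TMM and tested with edgeR 4.0.16 (glmQLFit with robust=TRUE, glmQLFTest, in R 4.3.3), with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Standard errors are the absolute log2 fold change over the square root of F. The interaction used all 36 libraries without a block, the region comparison used all 36 with preference as a covariate, and the animal as a replicate block was the alternative for each. The test over both regions used limma 3.58.1, voom with duplicateCorrelation over animals (consensus correlation 0.395). CPM values were scaled by TMM over all libraries, and log2 CPM used a prior count of 2. Principal components were computed on log2 CPM.

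The genes named were chosen by a rule set before the data were examined: within a region, the smallest p in each direction among genes that passed with a mean CPM of at least 1, or the smallest unadjusted p where fewer than 10 passed. For the interaction and the test over both regions the smallest p was used, and between regions the largest fold among passing genes of at least 10 CPM. At most 2 genes in each direction are printed because no symbols could be attached: 0 of the 32623 identifiers matched the gene table used here. For the same reason the 25 gene lists fixed beforehand, the cell type marker scores, the mitochondrial share, the oligodendrocyte covariate and the panel of named receptors and activity genes were not analysed here. Gene coordinates are not given.

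Alternatives set before the data were examined were DESeq2 1.42.0, RLE factors, no count filter, a mean CPM of at least 1, limma-voom, robust=FALSE, an adjusted p under 0.10, title code letters as a covariate, 1 surrogate variable (sva 3.50.0), all libraries in 1 fit, and leaving out each library. For PFC, 8 alternatives were added after the data were seen: 5 read-count covariates, 1 of them the first definition of the unassigned share, and 3 sets of animals left out. The first set tried was picked from the first principal component, which carries the outcome, and was replaced by the rule on the unassigned share. Ambiguous and not-unique shares depend in part on which genes are expressed, so those covariates can remove real differences. The same may hold for the unassigned share.

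The tests were checked on counts simulated from the real means, dispersions and library sizes, with 200 genes changed. Of 50 genes changed 1.25-fold, 27 were recovered in PFC and 33 in NAc, and of 50 changed 1.5-fold, 45 and 44. With 5 risk-averse PFC libraries, 17 of 50 genes changed 1.25-fold and 40 of 50 changed 1.5-fold were recovered. With all PFC libraries and the unassigned share as a covariate, 17 of 50 and 39 of 50 were. For the tests within a region the dispersions were estimated without the preference groups, so preference differences counted as dispersion. For the tests over 36 libraries the dispersions were estimated within the 4 groups, and the paired simulation gave each animal an effect common to its regions, sized by the measured correlation between them. Other splits of the samples were drawn with a fixed seed, 100 per comparison, 30 for the test over both regions and 80 for the interaction with the animal as a block.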

Results

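The series profiled gene expression in the brains of Sprague Dawley rats that had been sorted by how they chose in the rat gambling task. In this task a rat picks among 4 light signals in a touch-screen chamber, each tied to rewards and punishments of its own size and probability. Once choices had settled, animals were called risk-averse or risk-seeking. Total RNA was then extracted from the prefrontal cortex (PFC), a frontal cortical area, and from the nucleus accumbens (NAc), a part of the ventral striatum. Libraries prepared from it were sequenced. The 36 libraries came from 19 animals, 9 risk-averse and 10 risk-seeking, and formed 4 groups of 9. Both regions came from 17 animals, and 1 further risk-seeking animal gave each region. Counts over genes summed to between 18436025 and 34761269 per library. The deposited counts name genes only by Ensembl identifier, and the files do not pair these with symbols, so at most 2 identifiers in each direction are given per comparison.

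Read categories moved with risk preference, and these measured values stand beside every preference comparison that follows. The unassigned share is the part of uniquely aligned read pairs that was given to no annotated feature, which may include reads within introns. In PFC it was 25.01% ± 1.98 (SD, n = 9) in risk-averse and 23.3% ± 0.666 (SD, n = 9) in risk-seeking animals (two-sided exact permutation test, p = 0.0136, adjusted p = 0.0484 over 12 tests). In NAc it was 27.6% ± 2.61 and 25.7% ± 1.02 (SD, n = 9 each), which did not pass the same exact permutation test (p = 0.0535, adjusted p = 0.0917). The share of gene-overlapping pairs called ambiguous was lower in risk-averse animals in both regions. It was 0.655% ± 0.0417 against 0.719% ± 0.0331 in PFC (SD, n = 9 each, exact permutation p = 0.00354, adjusted p = 0.0212). In NAc it was 0.690% ± 0.0369 against 0.741% ± 0.0238 (SD, n = 9 each, exact permutation p = 0.00321, adjusted p = 0.0212). Alignments that were not unique made up 12.9% ± 0.535 in risk-averse and 13.5% ± 0.185 in risk-seeking PFC (SD, n = 9 each, exact permutation p = 0.0161, adjusted p = 0.0484), and 12.5% ± 0.391 and 12.8% ± 0.206 in NAc (exact permutation p = 0.0442, adjusted p = 0.0884). Gene counts, detected genes and the share of the 10 most abundant genes did not differ past the adjusted threshold in either region by the exact permutation test (lowest adjusted p = 0.0762).

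**Figure D1:**
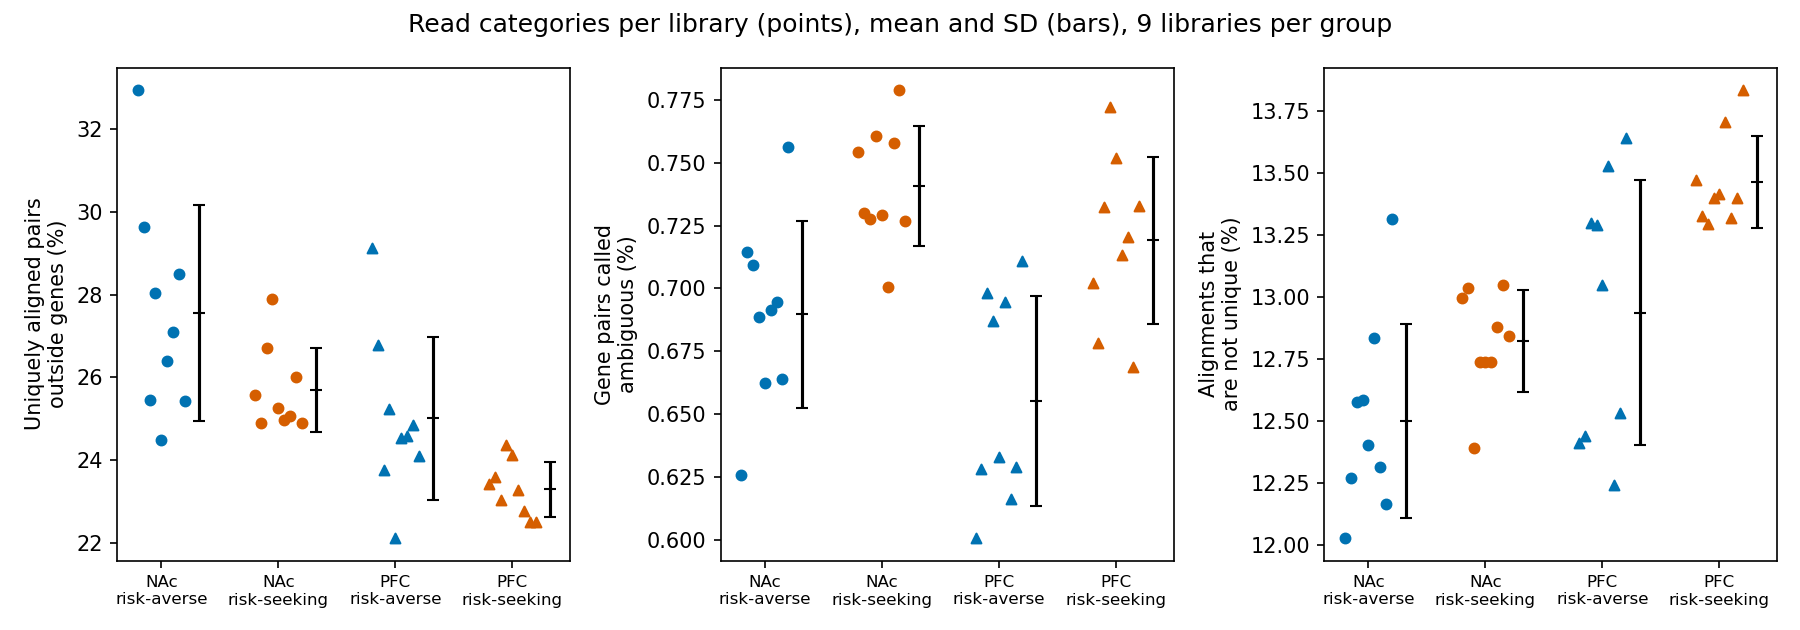
Each point is 1 library, with the percentage of reads in a category on the vertical axis and the 4 groups of 9 libraries on the horizontal axis, and bars give the mean and SD. Risk-averse PFC libraries averaged an unassigned share (pairs given to no annotated feature) of 25.01% against 23.3% in risk-seeking PFC, with the wider spread in the risk-averse group.

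The first comparison asked how the dissected regions differed. PFC and NAc differed in most of the genes measured: 11996 of 15470 passed edgeR's quasi-likelihood test at an adjusted p under 0.05, 5903 higher and 6093 lower in PFC. A difference of at least 2-fold was seen for 2468 of them, 1166 higher and 1302 lower in PFC. ENSRNOG00000016999 averaged 84.8 CPM in PFC and 0.616 CPM in NAc (log2 fold change 7.10 ± 0.12 (SE), adjusted p = 9.72e-36), and ENSRNOG00000010983 averaged 10.5 and 0.0909 CPM (6.80 ± 0.24, adjusted p = 1.66e-25). ENSRNOG00000010053 averaged 0.0875 CPM in PFC against 47.9 CPM in NAc (log2 fold change -8.97 ± 0.22, adjusted p = 4.85e-30). ENSRNOG00000028348 had 3 counts over the 18 PFC libraries and 7408 over the 18 NAc libraries, a ratio of 2300 with a 95% exact interval of 787 to 11200 that covers counting error only. The first principal component of all libraries held 72.04% of the variance and parted the regions.

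**Figure D2:**
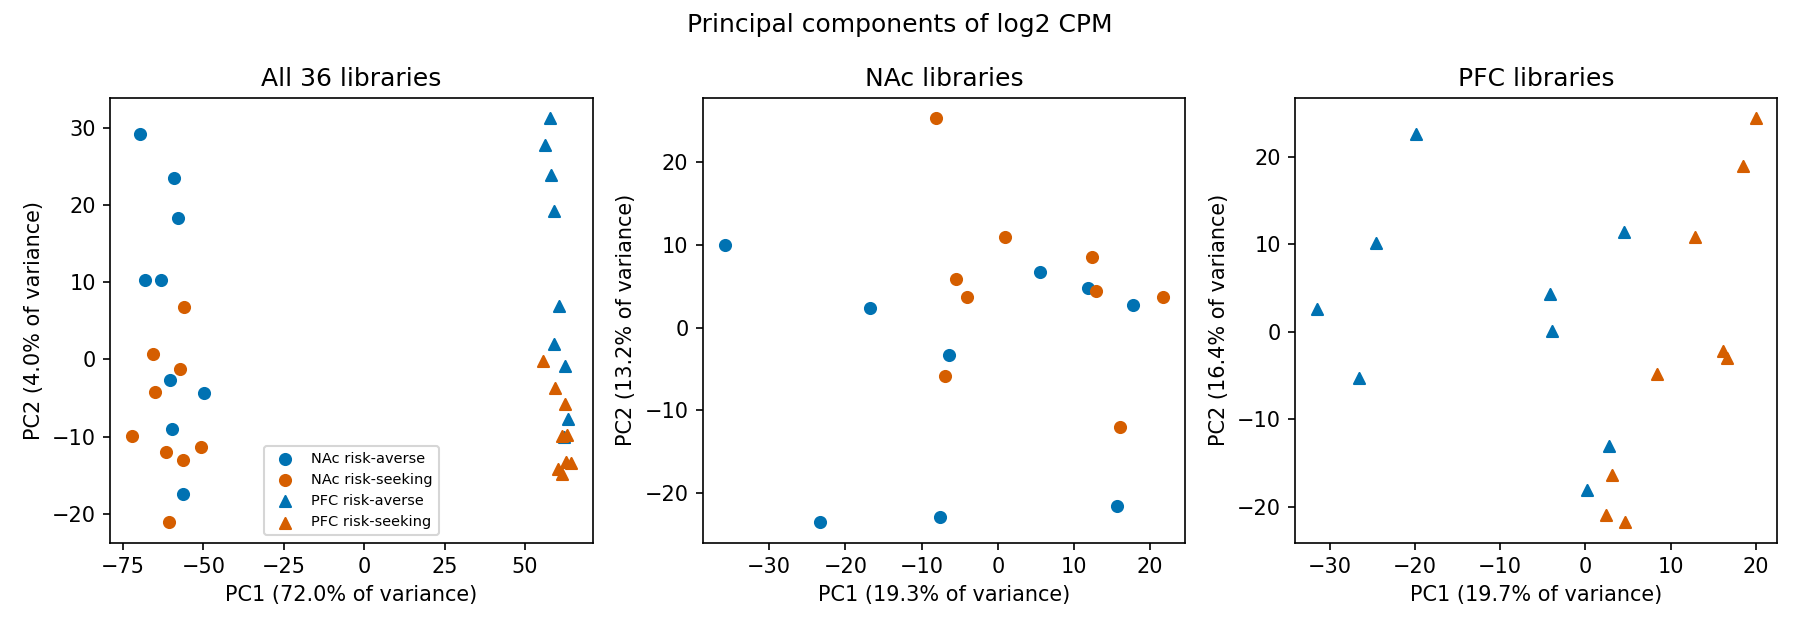
Points are libraries placed by the first 2 principal components of log2 CPM, for all 36 libraries, the NAc libraries and the PFC libraries. With all libraries, the first component (72.04% of the variance) separates PFC from NAc, and within PFC 4 risk-averse libraries lie lowest on the first component (19.7%).

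The next question was which genes differ between risk-seeking and risk-averse animals within PFC. Of 15128 genes tested, 3521 (23.3%) passed the edgeR quasi-likelihood test at an adjusted p under 0.05, 1791 higher and 1730 lower in risk-seeking animals. The differences were small: the median absolute log2 fold change of these genes was 0.25 (interquartile range 0.20 to 0.32), 102 reached 1.5-fold and 3 reached 2-fold. ENSRNOG00000007057 averaged 46.8 ± 3.96 CPM in risk-seeking and 76.6 ± 13.9 CPM in risk-averse PFC (SD, n = 9 each; log2 fold change -0.72 ± 0.09 (SE), edgeR adjusted p = 0.00106), and all 9 risk-seeking libraries lay below the risk-averse median. ENSRNOG00000007090 averaged 39.5 ± 2.23 and 54.5 ± 6.77 CPM (log2 fold change -0.48 ± 0.07, edgeR adjusted p = 0.00155). ENSRNOG00000038951 averaged 61.7 ± 3.35 CPM in risk-seeking and 48.6 ± 6.20 CPM in risk-averse PFC (log2 fold change 0.33 ± 0.06, edgeR adjusted p = 0.00275). ENSRNOG00000013468 averaged 29.1 ± 1.72 and 23.2 ± 2.40 CPM (log2 fold change 0.31 ± 0.06, edgeR adjusted p = 0.00275). For each of these 4 genes, 9 of 9 risk-seeking libraries lay on the stated side of the risk-averse median. Genes picked by the smallest p in these same libraries would mostly do so, so this adds no support. The 4 NAc genes named below, which did not pass, also had 9 of 9. With the ambiguous share as a covariate all 4 PFC genes lost their call (edgeR adjusted p = 0.761 each). Their log2 fold changes went from -0.720 to -0.499 for ENSRNOG00000007057, -0.475 to -0.292 for ENSRNOG00000007090, 0.334 to 0.171 for ENSRNOG00000038951 and 0.315 to 0.155 for ENSRNOG00000013468. ENSRNOG00000007090, ENSRNOG00000038951 and ENSRNOG00000013468 also lost it with the not-unique share (log2 fold changes -0.306, 0.218 and 0.2175, edgeR adjusted p = 0.0833, 0.212 and 0.220). Without the 4 animals of highest unassigned share the same 3 lost it at log2 fold changes of -0.381, 0.272 and 0.260 (edgeR adjusted p = 0.0873, 0.108 and 0.107), against -0.475, 0.334 and 0.315 with all libraries. All 4 passed with the unassigned share of uniquely aligned pairs (highest edgeR adjusted p = 0.0401). With that share over all alignments, the definition tried first, ENSRNOG00000038951 (0.285, edgeR adjusted p = 0.0501) and ENSRNOG00000013468 (0.242, edgeR adjusted p = 0.0533) lost their call. Called genes were most frequent among abundant genes, with 691 higher and 740 lower in the highest quartile of mean CPM against 89 and 142 in the lowest.

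The PFC count depended on the read categories and on a few animals. By alternatives chosen after the data were seen, it was 334 with the unassigned share as a covariate (43 higher, 291 lower), 76 with that share taken over all alignments, 0 with the ambiguous share, 1 with the not-unique share, 1 without the 4 animals of highest unassigned share, 1309 without the 2 highest, and 4 without the 4 animals lowest on the first principal component. Leaving out risk-averse animal B3 alone, an alternative set beforehand, gave 2264.

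**Figure D3:**
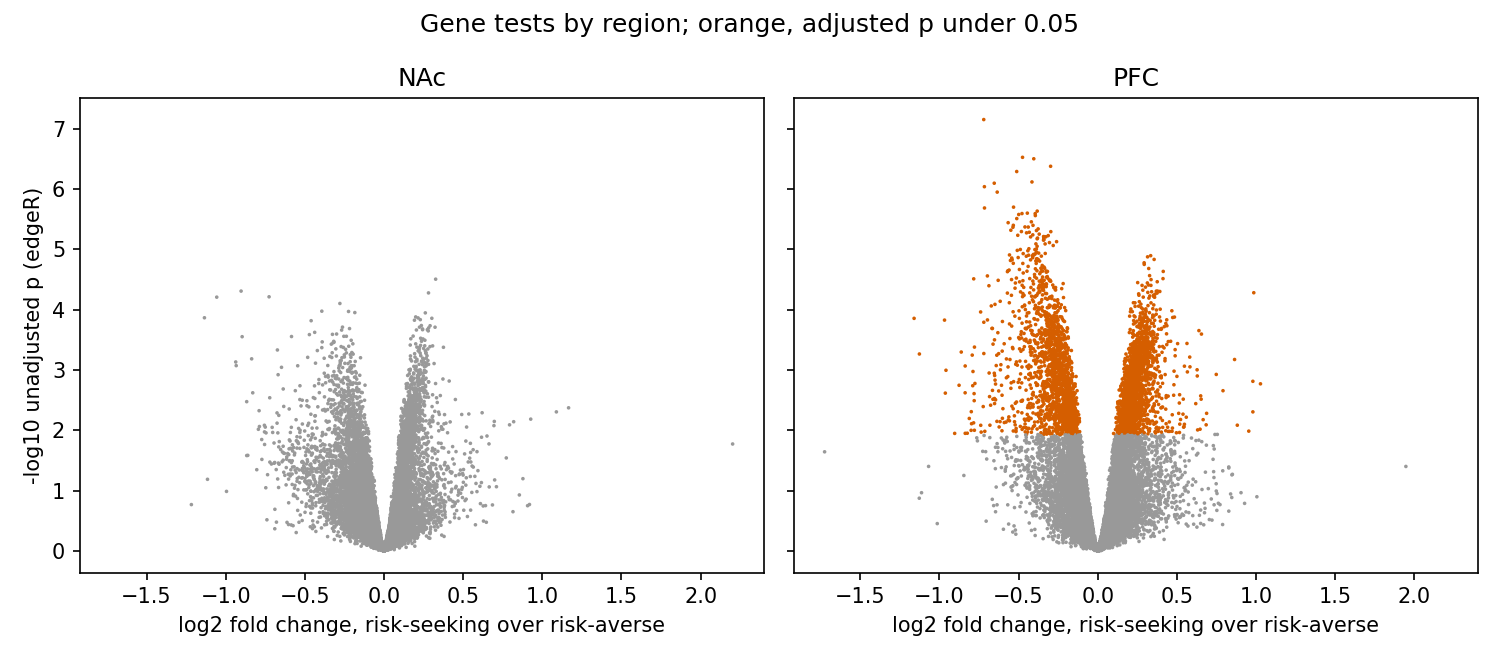
Each point is a gene, with the log2 fold change of risk-seeking over risk-averse animals on the horizontal axis and -log10 of the unadjusted edgeR p on the vertical axis, for NAc and PFC. Orange marks genes at an adjusted p under 0.05, of which there are 3521 in PFC and 0 in NAc.

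The same comparison within NAc called 0 of 15418 genes by edgeR at an adjusted p under 0.05. The lowest adjusted p was 0.0974, 278 genes lay under 0.10, and 2748 genes had an unadjusted p under 0.05, against a median of 693 over other splits of the 18 libraries, where 8 of 100 splits gave as many (highest other 3745). DESeq2 called 543 genes, and edgeR called 944 without risk-averse animal R9. None of the genes named next passed in edgeR with all 18 libraries. ENSRNOG00000042886 averaged 91.0 ± 7.71 CPM in risk-seeking and 72.2 ± 7.45 CPM in risk-averse NAc (SD, n = 9 each; log2 fold change 0.33 ± 0.06 (SE), edgeR adjusted p = 0.0974), and ENSRNOG00000000786 averaged 16.5 ± 0.768 and 13.5 ± 1.23 CPM (0.28 ± 0.06, edgeR adjusted p = 0.0974). ENSRNOG00000002511 averaged 0.508 ± 0.0722 and 0.944 ± 0.275 CPM (-0.90 ± 0.18, edgeR adjusted p = 0.0974), and ENSRNOG00000017277 averaged 2.31 ± 0.311 and 3.81 ± 1.01 CPM (-0.73 ± 0.15, edgeR adjusted p = 0.0974). Without R9 all 4 passed in edgeR (adjusted p = 0.0152 each), and ENSRNOG00000042886 and ENSRNOG00000000786 passed in DESeq2 (adjusted p = 0.00389 each), which gave no adjusted p for the other two. With read categories as covariates, chosen after the data were seen, the differences were smaller. With the ambiguous share the log2 fold changes were 0.139 for ENSRNOG00000042886, 0.147 for ENSRNOG00000000786, -0.633 for ENSRNOG00000002511 and -0.588 for ENSRNOG00000017277 (edgeR adjusted p = 1 each). Without the 4 animals of highest unassigned share they were 0.291, 0.225, -0.717 and -0.436 in the same order (edgeR adjusted p = 0.401 each).

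Whether the preference difference itself differed between regions was tested as an interaction over all 36 libraries. No gene of 15936 passed in edgeR (lowest adjusted p = 0.981), so the calls in PFC and their absence in NAc are not shown to differ. At an unadjusted edgeR p under 0.05 there were 387 genes, against a median of 196 over relabelled animals, where 15 of 100 labellings gave as many. Evenly spread p-values would give 796.8, so both numbers lay below that and the p-values of this fit ran high. This fit took the paired libraries of an animal as independent. With each animal as a replicate block, edgeR also called 0 genes, with 1770 at an unadjusted p under 0.05 (median 683 over relabelled animals, 8 of 80 labellings with as many) and a lowest adjusted p of 0.330. DESeq2 called 1. The smallest edgeR p belonged to ENSRNOG00000030763, which did not pass and averaged 0.267 CPM in risk-seeking and 0.472 CPM in risk-averse NAc against 12.2 and 10.2 CPM in PFC (edgeR adjusted p = 0.981). ENSRNOG00000052051, which did not pass either, averaged 29.6 and 27.9 CPM in NAc and 1.83 and 2.35 CPM in PFC (edgeR adjusted p = 0.981). In data simulated with paired libraries, the test without a block recovered 12 of 50 genes whose difference was 1.25-fold and 41 of 50 at 2-fold, and with the animal as a block 17 and 41, so differences of 1.25-fold between regions were mostly not detectable.

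Fold changes in the regions went the same way for most genes. Of the 3503 PFC calls tested in NAc, 3436 (98.1%) had the same sign there, against 79.2% of all 14765 genes tested in both, and 1700 also had an unadjusted p under 0.05 in NAc. The NAc fold change was a median 0.559 of the PFC one on the log2 scale. Sign agreement and a ratio above 0 arise without any preference effect, because most animals gave both regions. Over 99 relabellings of the 17 animals with both regions, the share of all genes with the same sign had a median of 63.0% and a highest value of 77.7%, against 79.1% with the true labels on log2 CPM differences. For the 3503 genes with the largest PFC statistic, chosen anew in each labelling by a check added after the data were seen, the share was 97.4% with the true labels against a median of 72.8% and a highest value of 93.4%. Their median ratio was 0.557 against a median of 0.367, and 15 of 100 labellings, the true one included, gave as high a ratio. Across genes, which are not independent replicates, the edgeR fold changes correlated at r = 0.659. The correlation is raised by the shared animals in the same way. On log2 CPM differences, r was 0.672 with the true labels, against a median of 0.368 and a highest value of 0.634 over the 99 relabellings. The covariance was 0.0198 against a median of 0.00537. With the unassigned share as a covariate, chosen after the data were seen, r was 0.528 against a highest relabelled value of 0.482.

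**Figure D4:**
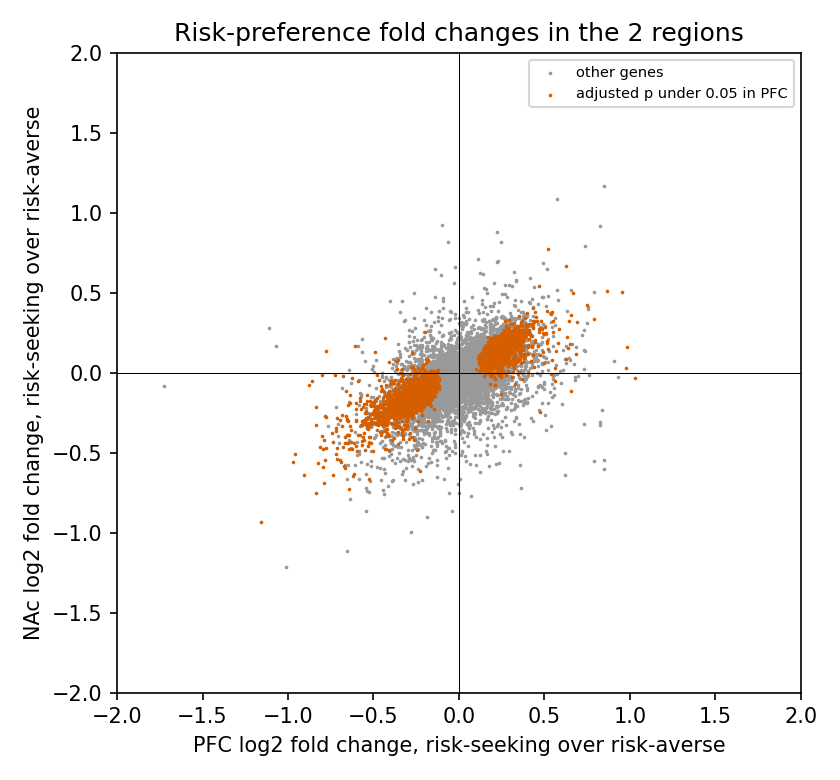
Each point is a gene tested in both regions, with the log2 fold change of risk-seeking over risk-averse animals in PFC on the horizontal axis and in NAc on the vertical axis, and 1 gene lies outside the axes. Genes called in PFC are orange, and 98.1% of them have the same sign in NAc. Relabelled animals gave up to 93.4% for as many genes of largest PFC statistic, where the true labels gave 97.4%.

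Taken over both regions, with the animal as a random effect in limma-voom, 3561 of 15936 genes passed at an adjusted p under 0.05, 1965 higher and 1596 lower in risk-seeking animals, with a median absolute log2 fold change of 0.20. The balance of directions turned with RLE factors (1729 higher, 1779 lower). ENSRNOG00000051190 had a log2 fold change of 0.32 ± 0.05 (SE, limma adjusted p = 0.000879) and ENSRNOG00000013468, also called in PFC alone, one of 0.28 ± 0.05 (limma adjusted p = 0.000879). ENSRNOG00000022305 and ENSRNOG00000001982 were lower in risk-seeking animals, with log2 fold changes of -0.33 ± 0.05 and -0.32 ± 0.05 (limma adjusted p = 0.000879 each). The count was 1486 with the unassigned share as a covariate (569 higher, 917 lower) and 7 without the 4 animals of highest unassigned share, both chosen after the data were seen. Without those animals, 2 of the 4 named genes lost their call: ENSRNOG00000051190 (log2 fold change 0.229, limma adjusted p = 0.0568) and ENSRNOG00000001982 (-0.276, limma adjusted p = 0.0541), while the other two were at 0.049 each.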

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

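The tests of fewer libraries and of which libraries, the covariates of gene counts and read categories, and the sets of animals left out were chosen only after the results were seen. The title code letters were set as a covariate beforehand, but the bound used to read their result was written afterwards. Of 86 groups of 9 libraries examined, 7 had a library far from the others, where about 4.3 would arise by chance. In risk-seeking NAc, animal BR4 had 12.4% of alignments not unique, against 12.74% to 13.05% in the others. ENSRNOG00000052051 was at 3.55 CPM in risk-averse PFC of animal BR9, against 1.93 to 2.56 CPM. ENSRNOG00000010983 was at 0.303 CPM in risk-averse NAc of B3, against at most 0.0890 CPM, and at 0.518 CPM in risk-seeking NAc of R1, against at most 0.173 CPM. ENSRNOG00000051190 was at 33.5 CPM in risk-seeking PFC of R2, against 39.5 to 45.3 CPM. ENSRNOG00000013468 was at 17.6 CPM in risk-averse NAc of B2, against 20.5 to 22.1 CPM, and ENSRNOG00000022305 at 36.2 CPM in risk-seeking PFC of B9, against 28.8 to 32.5 CPM.

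The pattern weighed first is the set of 3521 risk-preference calls in PFC. Chance labelling is unlikely: 1 of 100 splits of the 18 libraries, the real one, gave as many, and the highest other gave 1. The tables argue against unequal depth and the title code letters as the whole cause: of the 3521 calls, 2661 also passed with gene counts as a covariate (2688 called in all) and 3437 with the code letters (3824 called in all). Different dissection borders stay open. Region and preference fold changes correlated at 0.0579, inside the relabelled range of -0.0959 to 0.117, so the bound written beforehand against this explanation was met, by barely more than 1 SD (0.0581). That bound was too weak, since the range is wide and the test sees only tissue mixed between PFC and NAc, and this reading was chosen after the value was seen. The unassigned share stays open, because slopes on it within NAc groups correlated at -0.338 with the PFC difference, borderline against a shuffled 5th percentile of -0.311, while slopes within PFC groups gave -0.357 against -0.398. With slopes from 1 preference group alone, no value passed its 5th percentile: in PFC -0.388 for risk-averse (against -0.468) and 0.00155 for risk-seeking animals (against -0.164), and in NAc -0.331 (against -0.344) and -0.221 (against -0.285). Slopes within NAc groups correlated with the NAc preference difference, where 0 genes were called, at -0.359, below a 5th percentile of -0.276 (3 of 100 as low, the real one included). A real preference difference also stays open. The covariate fits below bear on it, but the read categories move with the preference groups and so do not separate the causes. Of the 4 named PFC genes, 0 lost their call with the unassigned share, 2 with that share over all alignments (the definition tried first), 3 with the not-unique share and 4 with the ambiguous share.

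With the unassigned share as a covariate, 322 of the 334 calls were among the 3521. The fold changes of the original calls shrank to a median 0.792 of their size while the median SE went from 0.0671 to 0.0740. Smaller folds with larger errors thus ended most calls. In simulated PFC data this covariate alone lowered the recovery of genes changed 1.25-fold from 27 to 17 of 50, so some loss of calls comes from lower power. With the ambiguous share the median ratio was 0.488 and with the not-unique share 0.542. Leaving out the 4 animals of highest unassigned share, B2, B3, BR9 and R7, all risk-averse, gave 1 call and a median ratio of 0.736. The tables argue against fewer libraries alone as the reason: of 99 other sets of 4 risk-averse animals left out, 58 shared at least 0.5 of the 3521 calls (median shared 2146), and the sets gave 0 to 5694 calls. The bound for this reading was written after the numbers of calls per set were seen, but before the shared calls were counted. Whether the 4 act as any other 4 was given a bound, fewer calls than every other set. The bound was not met, since 8 of the 99 sets gave as few calls, so the loss is not particular to the 4. The 8 sets shared a median of 3 animals with the 4, where 1.69 would be the mean for a drawn set. N6, whose PFC library had the lowest unassigned share (22.11%), was in 6 of the 8 and R4 (24.59%) in 5, as often as the 4 themselves (5 to 6). BR2 (23.76%), N7 (24.54%) and R9 (24.09%) were in 0 of the 8, against 47, 48 and 47 of the 99. Drawn sets that kept all 3 of these animals gave 0 to 4 calls, and sets that left out any of them gave at least 151. Among the risk-averse PFC libraries, BR2, N7 and R9 had the highest ambiguous shares (0.698%, 0.695% and 0.711%, next BR9 at 0.687%). Their not-unique shares were also the highest (13.30%, 13.53% and 13.64%, next BR9 at 13.29%). They lay highest of that group on the first principal component within PFC as well (0.177, 2.789 and 4.556). Which property of these animals matters was not tested. Over the sets, the number of calls and the mean unassigned share of the 5 risk-averse libraries used correlated at a Spearman rho of 0.454, given without a test because the sets overlap.

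The correlation of fold changes between regions is the other pattern weighed. Chance labelling is unlikely, since 1 of 100 labellings, the real one, gave a Pearson correlation as high as 0.672, and the highest other gave 0.634. This rests on the rank, since 0.672 exceeded the 95th percentile of the others (0.572) by less than 1 SD (0.104). With the unassigned share as a covariate in both regions the correlation was 0.528, which also ranked first, above the highest of 99 relabellings (0.482). The share moves with the true groups but was not tied to the relabelled ones, so this rank does not decide on chance. The correlation exceeded the 95th percentile of the relabellings (0.451) by less than 1 SD (0.0826). Because the share moves with the groups, it cannot be told apart from a preference effect common to both regions. The margin of 1 SD was set after the values were seen, and the bound written beforehand, a value above that percentile, was met. The covariate may also be an imperfect measure of whatever sets the share.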

How the results depend on the processing

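The covariates of read categories and gene counts, the sets of animals left out and the other denominator were chosen after the data were seen; the rest were set before the data were examined. In NAc, where edgeR called 0 genes (2748 at an unadjusted p under 0.05), DESeq2 called 543 and an adjusted p under 0.10 gave 278, and leaving out each library gave 0 to 944, with 17 of 18 at 0 and 944 without R9. The PFC count of 3521 stayed within 1.5 times under every alternative set beforehand except leaving out B3 (range over single libraries 2264 to 4227). It was 334 with the unassigned share, 76 with that share over all alignments, 0 with the ambiguous share (edgeR), 1 with the not-unique share, 4 without the 4 animals lowest on the first principal component, 1 without the 4 and 1309 without the 2 of highest unassigned share. The interaction gave 1 with DESeq2, and the replicate block (0 for the interaction, 12691 between regions) changed no call by over 1.5 times. Between regions 2468 remained with a 2-fold minimum. Over both regions 1486 were called with the unassigned share and 7 without the 4 animals. The correlation between regions was 0.527 with the unassigned share. Over all alignments, the unassigned share in NAc differed by -1.71 points (exact permutation p = 0.0489) against -1.86 (p = 0.0535). The cause was not tested for these changes, except as weighed for the PFC calls. No named gene changed sign, but 3492 of the 3521 PFC calls kept their sign with the ambiguous share. Higher calls outnumbered lower ones in PFC (1791 to 1730), but lower ones did in 12 of 18 fits leaving out a library, with RLE factors (1648 to 1819), DESeq2 (1946 to 2033) and no low-count filter (1355 to 1431), and in 7 of 8 added settings (43 to 291 with the unassigned share). Added settings with only 1 or 4 calls in all, as listed above, say little about direction. Over both regions the balance (1965 to 1596) turned with RLE factors (1729 to 1779), the unassigned share (569 to 917) and without the 4 animals (2 to 5). Of the named genes, 10 of 111 tests in NAc gained a call under alternatives set beforehand (4 without R9, 4 at an adjusted p under 0.10 and 2 in DESeq2), 0 lost their call under alternatives set beforehand, and under those added 15 of 32 tests in PFC and 2 of 8 over both regions did. The oligodendrocyte covariate and all alternatives for gene lists and marker scores were not run because no symbols could be attached.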

Other observations

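The test of the spread between libraries was prompted by the wider spread of the unassigned share in risk-averse animals, and the region groups were defined after the results were seen. Among genes at least 2-fold higher in either region, more were called lower than higher in risk-seeking PFC. Over all 15128 genes tested in PFC, 1791 were called higher and 1730 lower. Of 992 genes enriched in NAc, 23 were called higher and 91 lower (median log2 fold change -0.04), and of 1166 enriched in PFC, 44 were called higher and 152 lower (median -0.04). Camera gave an adjusted p of 0.0424 for each, and adjusted p = 0.49 and 0.43 with an estimated correlation, so neither camera call held. Fry, which does not compare a group with the other genes, gave unadjusted p = 0.0494 and 0.00734 in PFC. In NAc fry gave unadjusted p = 0.405 and 0.417 in the same order. A lean beyond that of other genes is therefore not shown. In NAc 0 genes of either group were called: the medians were -0.0193 for 1302 genes enriched in NAc and -0.0419 for 974 enriched in PFC, with camera adjusted p = 0.125 and 0.0424, and 0.537 for each with an estimated correlation.

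Some genes had levels that followed the animal. Over the 17 animals with both regions, 130 of 15936 genes correlated above 0.9 between NAc and PFC after group means were removed, where the highest of 100 mismatched pairings gave 1. Of the 130, 27 (20.8%) were called over both regions, against 22.4% of all genes.

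Libraries of risk-averse animals varied more, with a median ratio of SDs over genes of 1.13 in PFC and 1.19 in NAc. Relabelled animals gave ratios as far from 1 in 26 of 100 labellings in PFC (highest other 1.33) and 13 of 100 in NAc, so chance is not excluded.

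For the counts of 0 the splits decide nothing, since no split can give fewer: 100 of 100 splits gave as many calls in NAc (real 0, highest other 4), and 100 of 100 for the interaction (real 0, highest other 1). The genes at an unadjusted p under 0.05 were therefore counted over the same splits, a test chosen after the results were seen. In NAc, 8 of 100 splits gave as many as the real 2748 (highest other 3745), and for the interaction 15 of 100 gave as many as the real 387 (highest other 689), so chance is not excluded for either. With the animal as a replicate block, 8 of 80 relabellings gave as many as the real 1770 (highest other 2330), so chance is not excluded there either. The number of 80 was set by the time allowed, after a longer run had been seen. Chance is unlikely for the test over both regions, where 1 of 30 labellings, the real one with 3561 calls, gave as many. The highest other gave 4, though 30 labellings can give no rank lower than 1 in 30. Chance is also unlikely for PFC against NAc, where the real labelling gave 11996 calls, 1 of 100. The highest other gave 8325, a labelling that swapped 4 of 18 units (animals, or the pair with 1 region each) and so kept most region labels in place.

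The first principal component within NAc followed the unassigned share (Pearson r = -0.863, permutation p = 1e-05, the smallest 100000 resamples can give; Spearman rho = -0.796, permutation p = 0.00024; 8 relations computed, adjusted p = 8e-05). It held within risk-averse (r = -0.907, exact permutation p = 0.000661) and risk-seeking animals (r = -0.721, exact permutation p = 0.0176), and was -0.718 without the 2 farthest libraries. In PFC r was -0.649 (rho = -0.577, permutation p = 0.00345 and 0.0137, adjusted p = 0.0069 for r), but -0.532 within risk-averse (rho = -0.667, exact permutation p = 0.145 and 0.0589) and -0.0157 within risk-seeking animals (rho = 0.15, exact permutation p = 0.966 and 0.708). Without the 2 farthest libraries r was -0.475 (rho = -0.421, permutation p = 0.0628 and 0.107), so the PFC relation past the threshold rests in part on those libraries, and 9 libraries leave the relation within risk-averse animals open.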
